A study of Homo sapiens with 12 samples.

How the data were processed

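Polyadenylated RNA was sequenced from the PGP1 human induced pluripotent stem cell (iPSC) line and from 2 kinds of cells made from it. Per the labels' protocols, PGP1 cells received 12 µM CHIR99021, an inhibitor of the kinase GSK3 that turns on Wnt signalling, for 24 h from day 0 in insulin-free RPMI/B27 medium, and mesoderm was collected on day 2. Cultures kept for cardiomyocytes received 5 µM IWP-4, an inhibitor of Wnt secretion, for 48 h from day 3, then B27 with insulin from day 9 and metabolic selection from day 13, and were collected between days 25 and 30. RNA was extracted with Trizol and made into strand-marking TruSeq mRNA libraries that were read from a single end on an Illumina NextSeq. Each of the 3 groups had 4 libraries, 12 in all. The labels call them biological replicates. Whether they were separate differentiations is not given, so p-values measure only the spread between these libraries, which may be technical.

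The deposited values were raw whole-number counts for 60668 gene entries with versioned Ensembl identifiers, 1 column per library. Per the submitters' processing notes, Trimmomatic, STAR and StringTie were used with the GRCh38 build. Their versions and roles, the tool that made the counts, its strand setting and the annotation release were not given in the sources used here. Reads of genes overlapping on the other strand, or of near-identical copies, may thus have been divided differently. Values of MYH6 and MYH7 (adjacent paralogs), LEFTY1 and LEFTY2, HSPA1A and HSPA1B, and TUBB3 (overlapping locus) are uncertain for that reason. Identifiers matched a table of gene names for 99.39% of entries and GENCODE release 29 for 96.53% of entries, which held 99.95% of counts. The version suffix was the same for 68.96%. Positions are given on GRCh38 from GENCODE release 29, counted from 1. Of the entries, 24197 had 0 counts in every library. Genes of chromosome Y and XIST were used in totals and scaling and are not reported.

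Totals ran from 13.1 to 18.7 M counts in iPSC, 24.9 to 35.7 M in mesoderm and 21.7 to 28.2 M in cardiomyocyte libraries. A gene with 0 counts in a group was taken at a floor of 3 counts over the group's libraries, which is 0.0429 CPM (counts per M total counts) in iPSC, 0.0238 CPM in mesoderm and 0.0351 CPM in cardiomyocytes, and its change is given as at least the fold against that floor. Genes with 1 to 3 counts in a group are given as a ratio with a 95% counting interval. Intervals and floors cover counting error only. Replicate pairs were compared by a chi-square statistic per degree of freedom over genes with at least 20 counts in the pair. It lay between 4.18 and 388, so no pair was as alike as repeated sequencing of 1 library would be.

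Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (20077 genes), scaled by TMM, and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) in 1 fit of all 12 libraries with 9 residual degrees of freedom. The 3 comparisons were mesoderm against iPSC, cardiomyocyte against mesoderm and cardiomyocyte against iPSC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. CPM values use TMM-scaled totals, and log2 CPM a prior count of 2. Lists of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 35 lists and 3 comparisons together (105 tests), and again with an estimated correlation. Beside the calls over all genes, members were also adjusted over the list alone. Shares of each library's total were compared by a two-sided exact permutation test of 4 against 4 (70 assignments, smallest possible p 0.0286), adjusted over 15 tests. Genes called in both comparisons with mesoderm were set against independent lists, and counted in 6 divisions of its libraries into pairs.

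The design, the lists and the rule for named genes were fixed before the data were examined. All 35 lists are named in the results. A further 3 lists (heat shock proteins, unfolded protein response, and liver and foregut secreted proteins) were written after values were seen and are used only to describe single libraries. Some genes stand on more than 1 list.

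Genes are named by this rule. Per comparison, the 5 genes with the highest and the 5 with the lowest difference of mean log2 CPM were taken among called genes whose replicates did not overlap between groups, with a mean of at least 10 CPM in the higher group and a proper gene symbol. From each described list, the 2 called members with the largest absolute change, the called member with the largest change in the other direction and the member with the highest mean CPM were taken. POU5F1, NANOG, SOX2, TBXT, MIXL1, EOMES, MESP1, AXIN2, SOX17, NKX2-5, TNNT2, MYH6, MYH7, MYL2, NPPA, MKI67, COL1A1 and PECAM1 were always taken. The described lists numbered 10 for mesoderm against iPSC, 12 for cardiomyocyte against mesoderm and 11 for cardiomyocyte against iPSC, and every other list is given by its counts. Genes outside the rule were chosen after their values were seen, and the text says so. Some genes that the rule takes are not reported here.

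The procedure was tested on simulated counts with the real means and library sizes and 1 spread per gene for all libraries, so it holds no library that stands apart. Changed genes were drawn from those with a mean of more than 50 counts. Of genes changed by 1.5, 2 and 4 fold (67, 67 and 66 genes), edgeR called 10.4%, 38.8% and 90.9% for mesoderm against iPSC (20073 genes), 10.4%, 55.2% and 86.4% for cardiomyocyte against mesoderm (20054 genes) and 8.96%, 46.3% and 90.9% for cardiomyocyte against iPSC (20071 genes). Of its calls, 2.11%, 3.81% and 4.90% were false, in that order. DESeq2 1.42.0 gave 19.3%, 26.7% and 26.4% false calls on the same counts. Of 100 unchanged lists, camera at the preset correlation gave an unadjusted p under 0.05 for 2% in mesoderm against iPSC and 0% in the others. Alternatives were other scalings (median of ratios, upper quartile, library totals only), other filters on low counts, DESeq2, limma-voom, a test against a 2-fold change, fits of the 2 compared groups only, the replicate number as a block, mitochondrial or the 20 most abundant genes left out, entries of 1 symbol summed, and each library left out in turn. After the data were seen, 2 more were added, which left out 2 libraries together or weighted each by quality.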

Results

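Polyadenylated RNA was measured in 4 libraries each of PGP1 iPSC, mesoderm (day 2) and cardiomyocytes (days 25 to 30). Per library, 13.1 to 35.7 M counts and 24904 to 27454 genes were detected. The first principal component held 67.7% of the variance and the second 16.01%, and these set the 3 groups apart. The third held 7.05% and separated cardiomyocyte replicate 1 (-132) from the others (60.8, 36.1 and 36.7). The mean correlation of log2 CPM with the other libraries of the group was 0.978 to 0.980 in iPSC, 0.979 to 0.985 in mesoderm and 0.923 (replicate 1) to 0.961 in cardiomyocytes. The biological coefficient of variation was 10.8% in iPSC, 17.1% in mesoderm (10.7% without replicate 2) and 47.0% in cardiomyocytes (26.6% without replicate 1). These 2 libraries carry much of the spread, so counts of changed genes are also given without both (the doubted libraries below), a choice made after the data were seen.

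**Figure D1:**
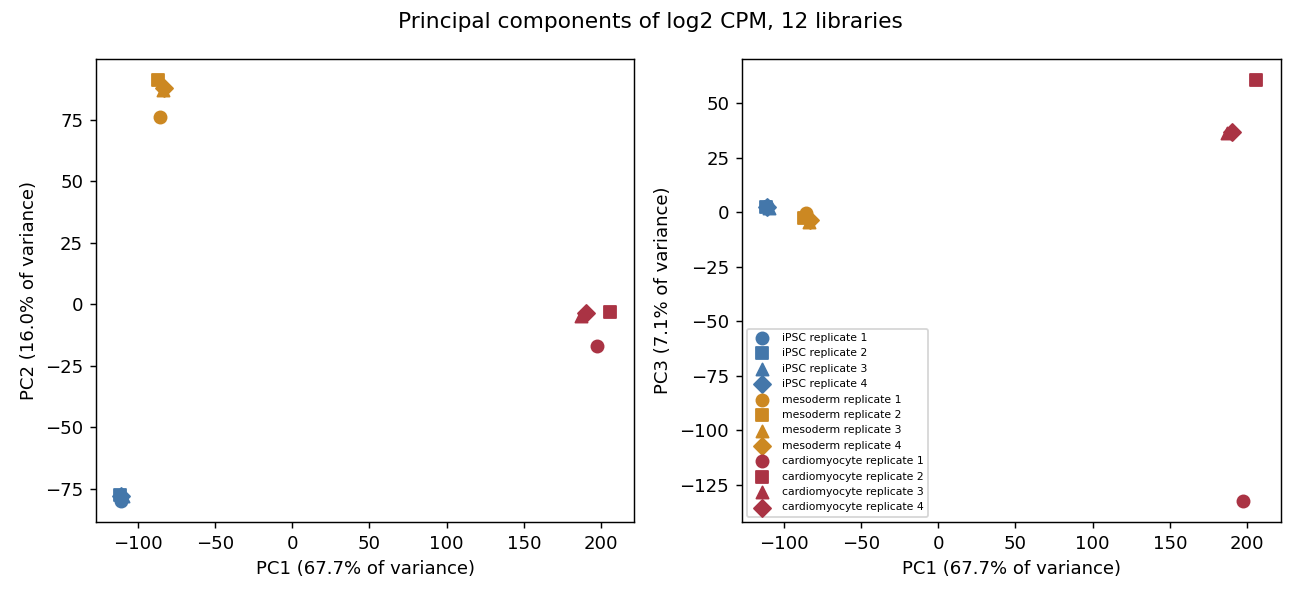
Principal components of log2 CPM over tested genes, 12 libraries: the first against the second component, and the first against the third. Each point is 1 library, coloured by group.

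**Figure D2:**
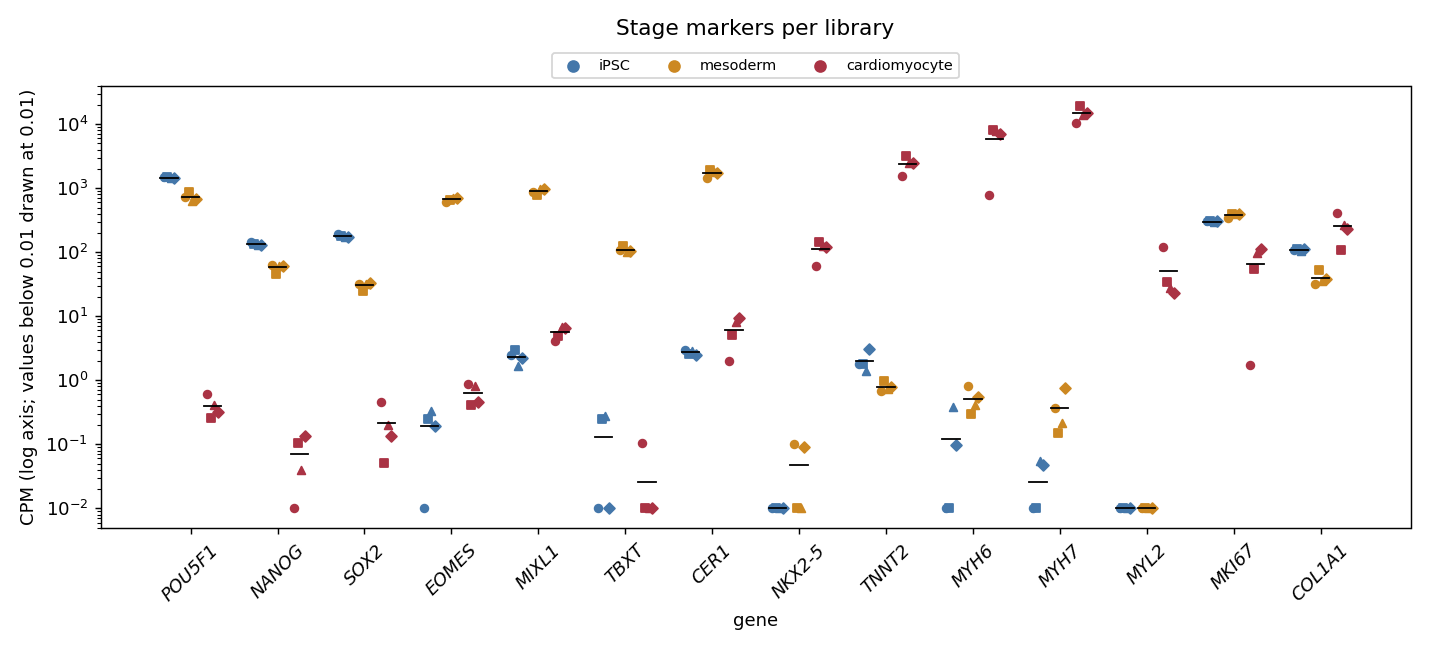
CPM of 14 genes in each library, log axis, 4 libraries per group. Values below 0.01 are drawn at 0.01. Black bars are group means, and marker shape gives the replicate: 1 circle, 2 square, 3 triangle, 4 diamond.

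The first question was what 2 days of differentiation, opened by a pulse of GSK3 inhibition, changed in iPSC. Genes of the primitive streak, the embryonic structure from which mesoderm and endoderm form, were switched on from near silence. EOMES (ENSG00000163508.13) (chromosome 3, 27715949 to 27722711), a T-box factor needed to form both layers, went from 0.192 ± 0.141 to 671 ± 40.6 CPM (mean ± SD, n = 4 per group here and below, log2 change 11.68, SE 0.39). MIXL1 (ENSG00000185155.11) (chromosome 1, 226223618 to 226227054), a streak homeobox factor, went from 2.34 ± 0.565 to 901 ± 90.3 CPM (8.59, SE 0.25). CER1 (ENSG00000147869.5) (chromosome 9, 14719724 to 14722717), a secreted antagonist of Nodal, BMP and Wnt, went from 2.72 ± 0.220 to 1717 ± 198 CPM (9.30, SE 0.46). TBXT (ENSG00000164458.9), the mesoderm factor Brachyury, went from 0.131 ± 0.151 to 109 ± 10.9 CPM (9.66, SE 0.52, and 10.36 without iPSC replicate 3). Several genes had 0 counts in all iPSC libraries. DKK4 (ENSG00000104371.5) (chromosome 8, 42374068 to 42377232), a Wnt antagonist, reached 525 ± 53.02 CPM (at least 12251-fold), the growth factor gene FGF17 (ENSG00000158815.11) (chromosome 8, 22042398 to 22048809) 378 ± 101 CPM (at least 8815-fold), the Wnt antagonist DKK1 (ENSG00000107984.10) 142 ± 29.2 CPM (at least 3314-fold) and the endoderm and heart factor GATA6 (ENSG00000141448.10) 90.4 ± 10.6 CPM (at least 2110.1-fold). MESP1 (ENSG00000166823.5), a factor of the earliest heart progenitors, was still low at 1.14 ± 0.305 CPM (at least 26.5-fold). For these genes the edgeR adjusted p (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) lay between 4.8e-09 (MIXL1) and 0.000828 (MESP1). Of the primitive streak and nascent mesoderm list, 25 of 28 members rose, 1 fell and 2 were not called (26 and 2 when adjusted over the list alone, median log2 change 7.90, or 7.02 with genes of 0 counts at their bound, camera adjusted p = 6.4e-69, and 6.8e-05 with an estimated correlation). The member that fell was LEFTY1 (ENSG00000243709.1), a Nodal antagonist that shares sequence with LEFTY2 (53.03 ± 8.80 to 29.9 ± 4.23 CPM, log2 change -0.83, SE 0.28, edgeR adjusted p = 0.0365). Its call was lost without iPSC replicate 1, 3 or 4 or mesoderm replicate 2, 3 or 4 (edgeR adjusted p 0.0803 to 0.0972) and with the replicate block (0.0613), and in each of those 6 leave-outs 0 members fell. It was 26 up and 1 down without the doubted libraries, and 2 fell without cardiomyocyte replicate 2.

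The Wnt pathway itself answered. Of the canonical Wnt targets and feedback list, 10 of 18 members rose, 2 fell and 6 were not called (the same over the list alone, median log2 change 1.70, camera adjusted p = 6.8e-10, and 0.0495 with an estimated correlation). It had 12 up and 2 down without the doubted libraries. AXIN2 (ENSG00000168646.13), a feedback inhibitor read widely as a gauge of Wnt activity, rose from 26.4 ± 5.63 to 63.9 ± 3.61 CPM (log2 change 1.28, SE 0.16, edgeR adjusted p = 0.000116). WIF1 (ENSG00000156076.10), which codes for a secreted Wnt inhibitor, fell from 3.58 ± 0.428 to 0.401 ± 0.126 CPM (-3.15, SE 0.28, edgeR adjusted p = 5.0e-05). In the Nodal and BMP pathway list 7 of 16 rose, 1 fell and 8 were not called (the same over the list alone, median 0.50, camera adjusted p = 0.0089, and 0.63 with an estimated correlation), with BMP2 (ENSG00000125845.7), a heart-inducing ligand, up from 0.670 ± 0.235 to 19.9 ± 2.44 CPM (4.90, SE 0.38, edgeR adjusted p = 3.4e-06). Without the doubted libraries 9 rose and 2 fell. The number that fell was 3 without cardiomyocyte replicate 1, 2 without cardiomyocyte replicate 2, and 0 without iPSC replicate 1, 3 or 4 or mesoderm replicate 2, 3 or 4. That list call was also lost with the replicate number as a block (camera adjusted p = 0.102).

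Genes of the pluripotent state fell by very different amounts. ZFP42 (ENSG00000179059.10), a marker of pluripotent cells, was nearly silenced (92.8 ± 4.23 to 0.152 ± 0.0479 CPM, log2 change -9.21, SE 0.19). SOX2 (ENSG00000181449.4) fell from 179.9 ± 10.2 to 30.7 ± 3.83 CPM (-2.55, SE 0.21). The core factors NANOG (ENSG00000111704.11) (135 ± 6.85 to 58.5 ± 8.11 CPM, -1.21, SE 0.18) and POU5F1 (ENSG00000204531.18) (chromosome 6, 31164337 to 31180731, 1458 ± 25.2 to 738 ± 108 CPM, -0.98, SE 0.15) about halved, and the DNA methyltransferase DNMT3B (ENSG00000088305.18) fell from 3172 ± 238 to 1021 ± 61.2 CPM (-1.64, SE 0.37). UTF1 (ENSG00000171794.4), a chromatin factor of stem cells, went from 9.63 ± 2.05 to 0.0535 ± 0.107 CPM (-7.31, SE 0.83, and -10.76 without mesoderm replicate 4). OTX2 (ENSG00000165588.17), a head and anterior streak factor on the same list, rose from 13.0 ± 0.339 to 141 ± 9.75 CPM (3.44, SE 0.43). These had edgeR adjusted p between 3.1e-08 (ZFP42) and 0.00458 (DNMT3B). In the pluripotency list 2 of 28 members rose, 18 fell and 8 were not called (3 and 18 over the list alone, median -0.95, camera adjusted p = 8.2e-11, and 0.0132 with an estimated correlation). The number that rose was 4 without the doubted libraries and without cardiomyocyte replicate 1 or 2 alone. Outside the described lists, the largest falls were of NNAT (ENSG00000053438.11), an imprinted gene of neural cells (75.9 ± 6.13 to 0.505 ± 0.156 CPM, log2 change -7.20, SE 0.36), the skeletal myosin gene MYH2 (ENSG00000125414.19) (57.1 ± 2.42 to 0.587 ± 0.398 CPM, -6.61, SE 0.93), the zinc finger gene ZNF492 (ENSG00000229676.3) (19.1 ± 2.30 to 0.137 ± 0.111 CPM, -7.03, SE 0.62) and the germ cell cyclin gene CCNA1 (ENSG00000133101.10) (20.6 ± 1.25 to 0.169 ± 0.144 CPM, -6.82, SE 0.71), and these had edgeR adjusted p from 1.8e-07 (NNAT) to 0.000239 (MYH2).

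Endoderm factors appeared in the same day-2 cultures. SOX17 (ENSG00000164736.6), an endoderm and vascular factor, had 0 counts in iPSC and reached 44.6 ± 15.5 CPM (at least 1041-fold, edgeR adjusted p = 0.000167), and FOXA2 (ENSG00000125798.14), a pioneer factor of endoderm and anterior streak, went from 2 counts to 74.7 ± 9.27 CPM (ratio 2616, 95% counting interval 724 to 21601, edgeR adjusted p = 1.6e-06, log2 change 11.11, and 13.81 without iPSC replicate 3). In the definitive endoderm list 9 of 15 members rose, 1 fell and 5 were not called (9 and 2 over the list alone, median 3.17, camera adjusted p = 0.00129, and 0.563 with an estimated correlation). It had 8 up and 1 down without the doubted libraries. The member that fell was the fetal liver gene AFP (ENSG00000081051.8) (1.31 ± 0.331 CPM in iPSC, 0 counts in mesoderm, at least 55.1-fold lower, edgeR adjusted p = 0.0331). Its call was lost without iPSC replicate 1, 2 or 3, any mesoderm library or cardiomyocyte replicate 1 (edgeR adjusted p 0.0504 to 0.116), with both doubted libraries out (0.188), with the replicate block (0.0543) and with limma-voom (0.263), and 0 members fell without iPSC replicate 1, 2 or 3 or any mesoderm library. The neuroectoderm list was divided, with 2 of 8 members up, 2 down and 4 not called (2 and 3 over the list alone, camera adjusted p = 0.908). The forebrain factor SIX3 (ENSG00000138083.5) reached 6.14 ± 2.80 CPM (at least 143-fold, edgeR adjusted p = 0.000719) and the Notch effector HES5 (ENSG00000197921.6) 0.560 ± 0.179 CPM (at least 13.1-fold, edgeR adjusted p = 0.00179), both from 0 counts. The neuronal gene STMN2 (ENSG00000104435.13) fell (2.97 ± 0.766 to 0.495 ± 0.198 CPM, log2 change -2.56, SE 0.80, edgeR adjusted p = 0.026), a call lost without iPSC replicate 1 or 3 or mesoderm replicate 1, 2 or 3 (edgeR adjusted p 0.0559 to 0.0708, with 1 that fell). With the doubted libraries or cardiomyocyte replicate 1 alone out, 4 members fell. TUBB3 (ENSG00000258947.7), at an overlapping locus, was not called (158 ± 18.4 and 104.7 ± 8.12 CPM, log2 change -0.59, SE 0.72, edgeR adjusted p = 0.565), but was called without cardiomyocyte replicate 2 (edgeR adjusted p = 0.00194).

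Presomitic mesoderm, the tissue of later somites, had no list call. In the presomitic and paraxial mesoderm list 2 of 9 members rose, 1 fell and 6 were not called (3 and 2 over the list alone, median 0.51, camera adjusted p = 0.632). The somite factor UNCX (ENSG00000164853.9) reached 0.607 ± 0.232 CPM from 0 counts (at least 14.2-fold, edgeR adjusted p = 0.0285), a call lost without iPSC replicate 3 or 4 or mesoderm replicate 2 or 3 (edgeR adjusted p 0.0514 to 0.0557). MEOX2 (ENSG00000106511.6), a muscle precursor factor, fell from 0.612 ± 0.128 CPM to 0 counts (at least 25.7-fold, edgeR adjusted p = 0.0006). LFNG (ENSG00000106003.13), a Notch modifier, was not called (19.96 ± 2.17 and 28.5 ± 4.67 CPM, log2 change 0.51, SE 0.34, edgeR adjusted p = 0.27), though it was without cardiomyocyte replicate 1 (edgeR adjusted p = 0.0253). These counts were fragile: 2 rose and 3 fell without the doubted libraries, 5 and 3 without cardiomyocyte replicate 1, 4 and 2 without cardiomyocyte replicate 2, and 1 and 2 without mesoderm replicate 2. Without mesoderm replicate 1, 4 rose, without mesoderm replicate 3, 1 rose, and without iPSC replicate 2, 2 fell.

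Mesenchymal genes rose, while the epithelial list was not called. CDH2 (ENSG00000170558.9) (N-cadherin) rose from 51.3 ± 1.94 to 638 ± 38.6 CPM (log2 change 3.64, SE 0.10, edgeR adjusted p = 4.8e-09), and the repressors of epithelial genes ZEB2 (ENSG00000169554.21) (0 counts to 5.11 ± 0.689 CPM, at least 119-fold, edgeR adjusted p = 0.000214) and ZEB1 (ENSG00000148516.21) (0.0655 ± 0.0809 to 1.31 ± 0.228 CPM, 4.11, SE 0.63, edgeR adjusted p = 0.000431, and 4.93 without iPSC replicate 3) appeared. In the mesenchymal transition list 9 of 14 members rose, 2 fell and 3 were not called (the same over the list alone and without the doubted libraries, median 0.99, camera adjusted p = 6.8e-05, and 0.139 with an estimated correlation). One that fell was TWIST2 (ENSG00000233608.4), a mesenchymal factor (2.61 ± 0.488 to 1.54 ± 0.116 CPM, -0.76, SE 0.21, edgeR adjusted p = 0.0208), a call lost without iPSC replicate 3 or 4 or mesoderm replicate 3 or 4 (edgeR adjusted p 0.0547 to 0.077, with 1 that fell) and with the replicate block (0.074). In the epithelial junction and adhesion list 0 of 15 rose, 3 fell and 12 were not called (the same over the list alone and without the doubted libraries, median -0.14, camera adjusted p = 0.591). The claudin gene CLDN3 (ENSG00000165215.6) fell from 4.05 ± 0.653 to 1.16 ± 0.339 CPM (-1.81, SE 0.44, edgeR adjusted p = 0.00759). CDH1 (ENSG00000039068.19) (E-cadherin) was not called (276 ± 9.42 and 501 ± 20.2 CPM, 0.86, SE 0.49, edgeR adjusted p = 0.193). Without cardiomyocyte replicate 2 it was called (edgeR adjusted p = 0.00379) and 2 members of the list rose.

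Heart regulators moved both ways by day 2. In the cardiac transcription factors list 10 of 25 rose, 5 fell and 10 were not called (11 and 5 over the list alone, median 0.43, or 0.35 with genes of 0 counts at their bound, camera adjusted p = 0.00175, and 0.139 with an estimated correlation or 0.0601 with the replicate block). Without the doubted libraries 12 rose and 3 fell, and 3 fell without iPSC replicate 2 or 4 or mesoderm replicate 3. Beside GATA6, HAND1 (ENSG00000113196.3), an early heart factor, reached 0.737 ± 0.186 CPM from 0 counts (at least 17.2-fold, edgeR adjusted p = 0.0116), SRF (ENSG00000112658.8), the partner of muscle coactivators, rose from 73.6 ± 2.03 to 98.8 ± 5.41 CPM (log2 change 0.43, SE 0.09, edgeR adjusted p = 0.00243) and MYOCD (ENSG00000141052.17), such a coactivator, fell from 2.87 ± 0.198 to 0.760 ± 0.291 CPM (-1.93, SE 0.38, edgeR adjusted p = 0.00206). NKX2-5 (ENSG00000183072.10) was not called (0 counts and 0.0481 ± 0.0557 CPM, edgeR adjusted p = 0.227), TNNT2 (ENSG00000118194.20) fell from 2.01 ± 0.730 to 0.794 ± 0.127 CPM (-1.36, SE 0.29, edgeR adjusted p = 0.00346), MYH7 (ENSG00000092054.13) had 2 counts in iPSC and 0.375 ± 0.275 CPM in mesoderm (ratio 13.1, 95% counting interval 3.64 to 109, edgeR adjusted p = 0.00725, log2 change 3.51, and 2.90 without mesoderm replicate 4), and MYH6 (ENSG00000197616.12) was not called (0.121 ± 0.183 and 0.516 ± 0.219 CPM, 1.97, SE 1.15, edgeR adjusted p = 0.205, and 0.0208 without cardiomyocyte replicate 1). MYL2 (ENSG00000111245.15) had 0 counts in both groups, and NPPA (ENSG00000175206.10) 0 counts in iPSC and 0.0336 ± 0.0672 CPM in mesoderm. The calls of HAND1, MYOCD and TNNT2 were lost with limma-voom (adjusted p 0.0842, 0.0686 and 0.0561). The proliferation gene MKI67 (ENSG00000148773.14) was not called (302 ± 2.67 and 382 ± 29.7 CPM, 0.34, SE 0.70, edgeR adjusted p = 0.749), but was called as higher with only the 2 groups fitted (edgeR adjusted p = 0.000998), as were CDH1 (4.35e-07) and LFNG (0.00649) as higher and TUBB3 (0.000279) as lower. The collagen gene COL1A1 (ENSG00000108821.13) fell from 109 ± 3.47 to 39.8 ± 8.86 CPM (-1.46, SE 0.31, edgeR adjusted p = 0.00366). The endothelial gene PECAM1 was too low to test, with at most 0.0479 CPM in any iPSC library and 0.303 CPM in any mesoderm library.

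Over all genes, 3573 rose and 3706 fell in mesoderm (36.3% of 20077, 1600 and 2283 of them by at least 2 fold, 431 and 445 by at least 8 fold). With the doubted libraries out 5808 rose and 5600 fell, and without cardiomyocyte replicate 1 alone 5642 and 5515. Scaled by library totals only, 2784 rose and 4413 fell (38.7% up instead of 49.1%, median of all genes -0.09), and by upper quartile 2914 and 4388 (39.9% up, median -0.08). In the remaining lists, p53 targets fell (0 of 14 up, 9 down, 0 and 12 over the list alone, camera adjusted p = 1.4e-05, and 0.0955 with an estimated correlation). No list call was made for the sarcomere and Z disc (11 up and 5 down of 38), calcium handling (4 and 1 of 16) and cardiac ion channels and connexins (5 and 7 of 25). None was made for atrial-type (3 and 1 of 10), ventricular-type (3 and 1 of 9), pacemaker-type (4 and 6 of 11), skeletal muscle (2 and 3 of 8) and smooth muscle (0 and 2 of 11). None was made for fibroblast and stroma (1 and 5 of 12), epicardial (0 and 1 of 6), endothelial (2 and 3 of 13), blood (1 and 0 of 3), cell division (0 and 0 of 24), DNA replication (4 and 0 of 22) and glycolysis (0 and 5 of 18). None was made for lactate oxidation and TCA cycle (2 and 5 of 26), fatty acid oxidation (4 and 4 of 25), nuclear respiratory chain (0 and 10 of 39), cholesterol synthesis (0 and 0 of 16), hypoxia response (3 and 2 of 14), splicing regulators of muscle and stem cells (4 and 1 of 19), cytosolic ribosomal proteins (3 and 0 of 30) and replication-dependent histones (0 and 2 of 5), with camera adjusted p from 0.176 (calcium handling) to 0.953 (cell division and endothelial). The fit includes the wider cardiomyocyte spread, so genes not called here may have changed. Some did not overlap, like CENPE (97 to 112 CPM in iPSC, 192 to 226 in mesoderm) and TPX2 (523 to 558, 299 to 331). Without cardiomyocyte replicate 1 the fibroblast and stroma list was called (camera adjusted p = 0.0462). Counts became 9 and 3 for calcium handling, 10 and 12 for ion channels, 3 and 2 for cell division, 8 and 2 for DNA replication and 2 and 9 for glycolysis. Then 6 atrial-type, 8 lactate and TCA, 7 fatty acid and 10 ribosomal protein genes rose, and 6 smooth muscle and 4 splicing genes fell. With iPSC replicate 2, 3 or 4 or mesoderm replicate 3 or 4 left out, 5 or 6 respiratory chain genes fell. With 1 library left out, other counts here moved by over 1.5 times only where that was at most 2 genes. Without both doubted libraries 17 respiratory chain genes fell and 4 rose, and 10 lactate and TCA, 12 ribosomal protein and 7 splicing genes rose. Scaled by library totals or upper quartile, 0 ribosomal protein genes rose. In the mitochondrial genome list 1 of 13 rose and 0 fell (camera adjusted p = 0.42), but 8 rose without mesoderm replicate 2 (camera adjusted p = 0.000433, median 0.66) and 12 without both doubted libraries.

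**Figure D3:**
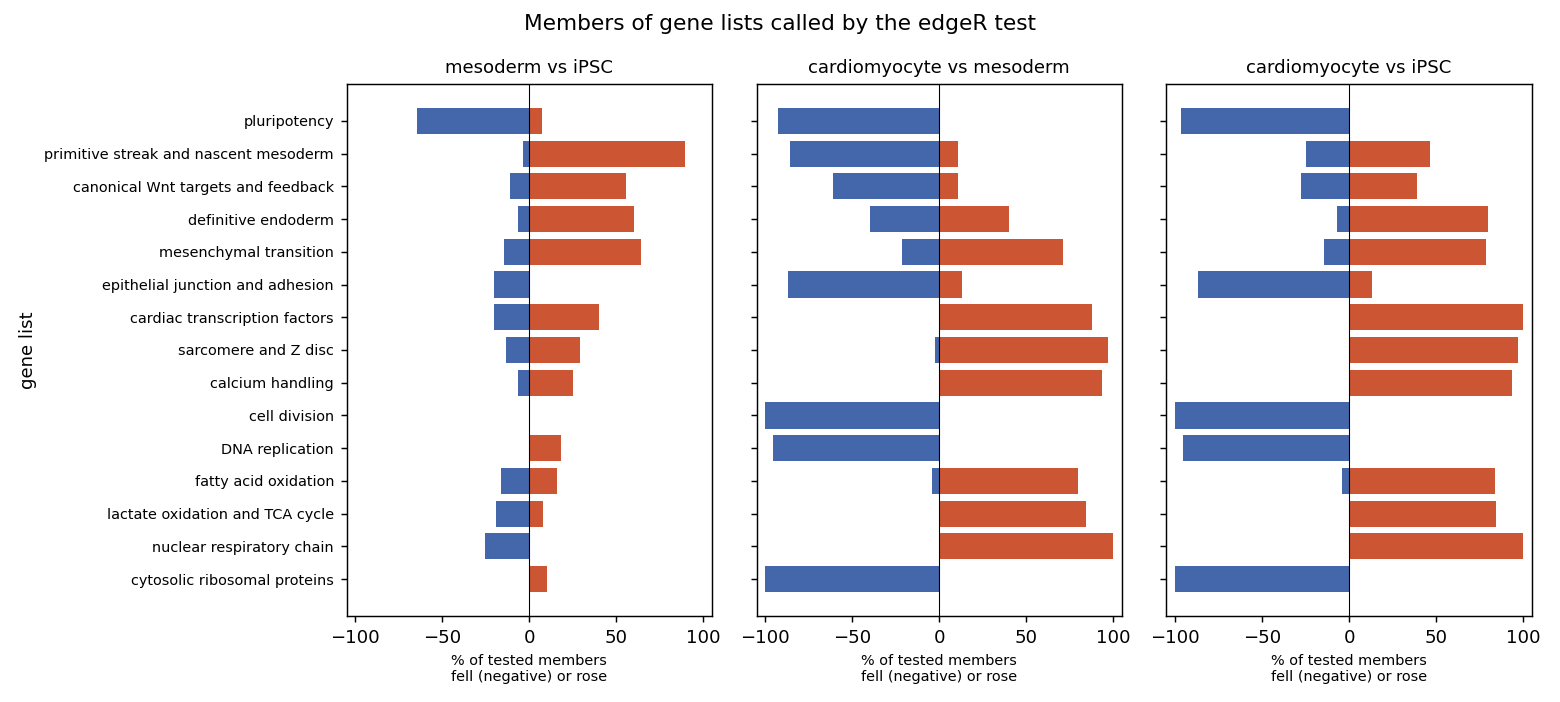
Percent of tested members that rose (up) and fell (down) at an edgeR adjusted p under 0.05 in 15 gene lists, for each of the 3 comparisons, 4 libraries per group.

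The second question was which genes separate cardiomyocytes from the day-2 mesoderm. The contractile apparatus of the heart went from almost nothing to some of the most abundant messages. MYH7 (chromosome 14, 23412738 to 23435718), the slow myosin heavy chain, went from 0.375 ± 0.275 to 14766 ± 3676 CPM (log2 change 15.23, SE 0.54, and 15.82 without mesoderm replicate 4). Its neighbour MYH6 (chromosome 14, 23381990 to 23408277) went from 0.516 ± 0.219 to 5911 ± 3439 CPM (13.47, SE 0.96). The giant spring gene TTN (ENSG00000155657.26) (chromosome 2, 178525989 to 178830802) went from 13.3 ± 1.30 to 19082 ± 4189.6 CPM (10.48, SE 0.23), and TNNT2, cardiac troponin T, from 0.794 ± 0.127 to 2429 ± 663 CPM (11.58, SE 0.37). From 0 counts in mesoderm, MYBPC3 (ENSG00000134571.11), a myosin-binding protein gene mutated in cardiomyopathy, reached 1508 ± 501 CPM (at least 63233-fold), the Z-disc gene MYOZ2 (ENSG00000172399.5) 655 ± 448 CPM (at least 27487-fold) and MYL2, the ventricular light chain, 51.1 ± 45.3 CPM (at least 2143-fold, with 119 CPM in replicate 1 and 23.4 to 34.8 CPM in the others, log2 change 13.23, and 12.41 without it). CSRP3 (ENSG00000129170.10), a stretch sensor of the Z disc, went from 0.0274 ± 0.0548 to 1474 ± 1437 CPM (15.29, SE 1.15, 14.32 without cardiomyocyte replicate 1 and 17.99 without mesoderm replicate 3). These had edgeR adjusted p between 2.8e-11 (TTN) and 0.000231 (MYL2). In the sarcomere and Z disc list 37 of 38 members rose, 1 fell and 0 were not called (the same over the list alone and without the doubted libraries, median 11.06, or 10.65 with genes of 0 counts at their bound, camera adjusted p = 8.1e-47, and 2.4e-06 with an estimated correlation). The 1 that fell was MYOM2 (ENSG00000036448.10), a gene of the mature M band (0.771 ± 0.322 to 0.251 ± 0.108 CPM, -1.61, SE 0.50, edgeR adjusted p = 0.0136). Sarcomere genes held 8.75 ± 0.824% of counts in cardiomyocytes, 0.0550 ± 0.00282% in mesoderm and 0.0634 ± 0.000483% in iPSC (exact permutation p = 0.0286 for each pair of groups, n = 4 per group, adjusted p = 0.0476).

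Regulators of the heart programme rose with it. NKX2-5, a core heart factor, went from 0.0481 ± 0.0557 to 112 ± 35.7 CPM (log2 change 11.05, SE 0.58). SMYD1 (ENSG00000115593.15), a muscle methyltransferase, went from 0.0443 ± 0.0581 to 1765 ± 611 CPM (15.03, SE 0.68, and 15.99 without mesoderm replicate 4), and TBX2 (ENSG00000121068.14), a repressor of chamber genes, from 0 counts to 26.9 ± 12.6 CPM (at least 1129-fold), and these had edgeR adjusted p from 5.5e-09 (SMYD1) to 4.6e-05 (TBX2). In the cardiac transcription factors list 22 of 25 rose, 0 fell and 3 were not called (23 and 1 over the list alone, median 5.41, camera adjusted p = 5.1e-14, and 0.00452 with an estimated correlation). Without the doubted libraries 23 rose, and 1 fell without iPSC replicate 2 or 3, mesoderm replicate 1 or cardiomyocyte replicate 4. NPPA, the atrial natriuretic peptide gene, went from 0.0336 ± 0.0672 to 1339.9 ± 1635 CPM (15.13, SE 1.72, edgeR adjusted p = 5.6e-05), with 3742, 83.1, 859 and 676 CPM in the 4 libraries. Its log2 change was 13.82 without cardiomyocyte replicate 1 and 17.89 without mesoderm replicate 1.

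Genes of calcium handling also rose. PLN (ENSG00000198523.6), the brake of the calcium pump, went from 0.0893 ± 0.0702 to 2217 ± 985 CPM (log2 change 14.44, SE 0.70). JPH2 (ENSG00000149596.6), which ties the cell membrane to calcium stores, went from 0.813 ± 0.131 to 268 ± 38.9 CPM (8.36, SE 0.17). The pump gene ATP2A2 (ENSG00000174437.17) went from 360.3 ± 16.4 to 2418 ± 163 CPM (2.75, SE 0.09), and these had edgeR adjusted p from 2.0e-11 (JPH2) to 2.1e-07 (PLN). In the calcium handling list 15 of 16 rose, 0 fell and 1 was not called (the same over the list alone and without the doubted libraries, median 5.02, camera adjusted p = 6.3e-15, and 0.0132 with an estimated correlation). Ion channels were mixed, with 14 of 25 members of the cardiac ion channels and connexins list up, 7 down and 4 not called (the same over the list alone, median 1.81, camera adjusted p = 0.0176). That list call was lost with an estimated correlation (camera adjusted p = 0.0955), with the replicate block (0.0716) and without mesoderm replicate 2 (0.0558), and 8 fell without the doubted libraries. The potassium channel genes KCND3 (ENSG00000171385.9) (3 counts to 6.17 ± 8.37 CPM, ratio 259, 95% counting interval 88.5 to 1254, 18.7 CPM in replicate 1 and 0.978 to 2.63 in the others, log2 change 7.74, 6.12 without replicate 1, and 10.09 without mesoderm replicate 3) and KCNJ5 (ENSG00000120457.12) (1.98 ± 0.985 to 89.8 ± 54.4 CPM, 5.50, SE 0.69) rose. The connexin gene GJA1 (ENSG00000152661.9), which couples neighbouring cells, fell from 879 ± 147 to 180.5 ± 68.1 CPM (-2.28, SE 0.26). For these, edgeR adjusted p ran from 9.5e-06 (GJA1) to 0.000337 (KCND3).

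The streak programme fell to low levels. DKK4 fell from 525 ± 53.02 CPM to 0 counts (at least 14948-fold), the glutamate receptor gene GRM4 (ENSG00000124493.13) from 170.3 ± 16.4 CPM to 0 counts (at least 4848-fold) and the organizer factor GSC (ENSG00000133937.4) from 54.3 ± 12.6 CPM to 0 counts (at least 1545-fold). FGF17 fell from 378 ± 101 to 0.136 ± 0.173 CPM (log2 change -11.45, SE 0.62). FGF4 (ENSG00000075388.4) went from 329 ± 20.7 to 0.155 ± 0.179 CPM (-11.12, SE 0.50). The retinoic acid hydroxylase gene CYP26A1 (ENSG00000095596.12) went from 319 ± 52.7 to 0.191 ± 0.221 CPM (-10.62, SE 0.59). EOMES went from 671 ± 40.6 to 0.639 ± 0.238 CPM (-10.02, SE 0.35). CER1 went from 1717 ± 198 to 6.11 ± 3.24 CPM (-8.13, SE 0.43). MIXL1 went from 901 ± 90.3 to 5.61 ± 1.31 CPM (-7.32, SE 0.24). MESP1 went from 1.14 ± 0.305 to 0.222 ± 0.163 CPM (-2.28, SE 0.58). TBXT fell from 109 ± 10.9 CPM to 2 counts (ratio 4654, 95% counting interval 1288 to 38432), and the endoderm factor SOX17 from 44.6 ± 15.5 to 1.01 ± 0.889 CPM (-5.43, SE 0.77). Without cardiomyocyte replicate 1 the log2 changes were -12.49 for FGF17, -11.74 for FGF4 and -14.34 for TBXT (-11.88 with it). Without cardiomyocyte replicate 2 FGF4 had -11.73, and without cardiomyocyte replicate 3 CYP26A1 had -11.36. Against this, RSPO3 (ENSG00000146374.14), a Wnt-enhancing ligand, rose from 12.0 ± 1.96 to 142 ± 90.1 CPM (3.56, SE 0.69). These had edgeR adjusted p between 2.5e-10 (GRM4) and 0.007 (MESP1). In the primitive streak and nascent mesoderm list 3 of 28 rose, 24 fell and 1 was not called (3 and 25 over the list alone, median -6.51, or -5.96 with genes of 0 counts at their bound, camera adjusted p = 9.5e-18, and 0.00965 with an estimated correlation), the same without the doubted libraries. Wnt targets fell back, with 2 of 18 in the canonical Wnt targets and feedback list up, 11 down and 5 not called (the same over the list alone, median -2.03, camera adjusted p = 0.00235, and 0.291 with an estimated correlation). With the doubted libraries out 4 rose and 12 fell, and 4 rose without cardiomyocyte replicate 1. AXIN2 fell from 63.9 ± 3.61 to 13.5 ± 2.11 CPM (-2.25, SE 0.17). SP5 (ENSG00000204335.4), a direct Wnt target, went from 114 ± 24.2 to 0.188 ± 0.144 CPM (-9.13, SE 0.46). The receptor gene TNFRSF19 (ENSG00000127863.15) rose from 1.16 ± 0.118 to 482 ± 359.8 CPM (8.69, SE 0.85), and these had edgeR adjusted p from 1.3e-08 (SP5) to 2.9e-06 (TNFRSF19).

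Pluripotency factors, still present on day 2, were lost too. POU5F1 fell from 738 ± 108 to 0.400 ± 0.158 CPM (log2 change -10.84, SE 0.24). NANOG went from 58.5 ± 8.11 to 0.0702 ± 0.0617 CPM (-9.60, SE 0.31). SOX2 went from 30.7 ± 3.83 to 0.214 ± 0.178 CPM (-7.15, SE 0.31, and -7.77 without cardiomyocyte replicate 1), and these had edgeR adjusted p from 2.8e-11 (POU5F1) to 4.3e-09 (SOX2). Of the pluripotency list, 0 of 28 rose and 26 fell (camera adjusted p = 2.6e-28, and 9.4e-04 with an estimated correlation). Genes of the cell cycle fell together. MKI67 went from 382 ± 29.7 to 66.5 ± 49.2 CPM (-2.52, SE 0.74). The mitotic kinase gene AURKB (ENSG00000178999.13) went from 73.6 ± 8.57 to 6.02 ± 4.52 CPM (-3.60, SE 0.62). The kinesin gene CENPE (ENSG00000138778.12) went from 215 ± 15.8 to 21.7 ± 15.2 CPM (-3.31, SE 0.51). The topoisomerase gene TOP2A (ENSG00000131747.15) went from 652 ± 42.0 to 86.9 ± 65.6 CPM (-2.91, SE 0.69). The replication licensing gene CDT1 (ENSG00000167513.9) went from 81.9 ± 18.7 to 4.05 ± 2.18 CPM (-4.33, SE 0.43). The nucleotide synthesis gene RRM2 (ENSG00000171848.15) went from 126 ± 8.85 to 11.9 ± 7.97 CPM (-3.40, SE 0.56). The helicase gene MCM3 (ENSG00000112118.20) went from 358 ± 42.6 to 101 ± 43.1 CPM (-1.82, SE 0.29), and these had edgeR adjusted p from 3.1e-06 (CDT1) to 0.00976 (MKI67). In the cell division list 24 of 24 fell (24 over the list alone, median -2.40, camera adjusted p = 0.00364, and 0.793 with an estimated correlation) and in the DNA replication list 21 of 22 fell, 0 rose and 1 was not called (21 over the list alone, median -2.08, camera adjusted p = 1.7e-05, and 0.563 with an estimated correlation), the same counts without the doubted libraries.

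Genes of fatty acid use rose. The coactivator gene PPARGC1A (ENSG00000109819.9), which drives the making of mitochondria, rose from 1.02 ± 0.198 to 167 ± 36.6 CPM (log2 change 7.36, SE 0.21). The fatty acid carrier gene FABP3 (ENSG00000121769.8) went from 3.48 ± 0.359 to 361 ± 56.3 CPM (6.69, SE 0.16). HADHA (ENSG00000084754.12), an enzyme of fatty acid oxidation, went from 220.0 ± 13.95 to 377 ± 59.2 CPM (0.78, SE 0.11). CPT1A (ENSG00000110090.13), the liver form of the entry enzyme, fell from 64.3 ± 1.77 to 32.1 ± 13.1 CPM (-1.002, SE 0.22). The edgeR adjusted p of these genes lay between 4.9e-11 (FABP3) and 0.00139 (CPT1A). In the fatty acid oxidation list 20 of 25 rose, 1 fell and 4 were not called (22 and 1 over the list alone, median 1.28, camera adjusted p = 4.6e-09, and 0.31 with an estimated correlation). It had 22 up and 1 down without the doubted libraries.

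Genes of other cell types were mixed. The smooth muscle list rose, with 9 of 11 up, 1 down and 1 not called (9 and 1 over the list alone, median 3.33, camera adjusted p = 3.2e-04, and 0.235 with an estimated correlation). The number that fell was 2 without the doubted libraries and without cardiomyocyte replicate 1. These genes also serve immature heart muscle: ACTA2 (ENSG00000107796.13) rose from 1.32 ± 0.245 to 658 ± 299.9 CPM (log2 change 8.96, SE 0.40). LMOD1 (ENSG00000163431.13) went from 0.752 ± 0.0546 to 195 ± 45.6 CPM (8.02, SE 0.22). TAGLN (ENSG00000149591.17) went from 141 ± 14.9 to 1416 ± 1088 CPM (3.33, SE 0.48, and 2.69 without cardiomyocyte replicate 1). The kinase gene MYLK (ENSG00000065534.18) fell from 24.9 ± 1.87 to 7.99 ± 4.41 CPM (-1.63, SE 0.32), and these had edgeR adjusted p from 1.3e-10 (LMOD1) to 0.000721 (MYLK). In the fibroblast and stroma list 6 of 12 rose, 3 fell and 3 were not called (6 and 4 over the list alone, median 0.43, camera adjusted p = 0.524), the same without the doubted libraries. COL1A1 rose from 39.8 ± 8.86 to 256 ± 128 CPM (2.69, SE 0.33). COL1A2 (ENSG00000164692.17) went from 219 ± 28.3 to 533 ± 278 CPM (1.28, SE 0.32). COL3A1 (ENSG00000168542.14) went from 0.158 ± 0.0829 to 216 ± 327 CPM (10.36, SE 1.28, and 8.32 without cardiomyocyte replicate 1). The matrix gene LUM (ENSG00000139329.5) went from 3 counts to 34.4 ± 51.9 CPM (ratio 1443, 95% counting interval 494 to 6997), with 112 CPM in replicate 1 and 3.04 to 14.3 CPM in the others (log2 change 10.22, 8.21 without that library, and 12.57 without mesoderm replicate 3). The surface gene THY1 (ENSG00000154096.13) fell from 58.4 ± 3.84 to 1.76 ± 2.14 CPM (-5.07, SE 0.58, and -6.38 without cardiomyocyte replicate 1). These had edgeR adjusted p from 1.1e-05 (THY1) to 0.00376 (COL1A2). In the endothelial list 2 of 13 rose, 7 fell and 4 were not called (2 and 7 over the list alone, median -1.17, camera adjusted p = 0.294). KDR (ENSG00000128052.10), a vascular receptor gene that also marks early mesoderm, fell from 427 ± 12.8 to 104 ± 55.3 CPM (-2.03, SE 0.38). VWF (ENSG00000110799.13) went from 5.37 ± 1.60 CPM to 0 counts (at least 153-fold), while the junction gene ESAM (ENSG00000149564.12) went from 0 counts to 6.22 ± 2.44 CPM (at least 261-fold), and these had edgeR adjusted p from 4.5e-07 (VWF) to 0.000542 (KDR). PECAM1 was too low to test, with 0, 1.08, 0.323 and 0.595 CPM in the cardiomyocyte libraries. In that list 4 rose and 6 fell without the doubted libraries, 4 rose without cardiomyocyte replicate 1, and 1 rose without cardiomyocyte replicate 2, 3 or 4.

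Over all genes, 6425 were higher and 7007 lower in cardiomyocytes than in mesoderm (66.9% of those tested, 4231 and 4815 by at least 2 fold, 1222 and 1691 by at least 8 fold), and 7314 and 8153 without the doubted libraries. Scaled by library totals only the numbers were 5127 and 8473 (37.7% up instead of 47.8%, median of all genes -0.31), and the median was -0.13 by upper quartile. Of the lists not described above, those called were the presomitic and paraxial mesoderm (0 up and 6 down of 9, camera adjusted p = 0.00185, and 0.209 with an estimated correlation), atrial-type (6 and 0 of 10, 0.00116, and 0.0374), ventricular-type (9 and 0 of 9, 2.1e-07, and 0.0955), lactate oxidation and TCA cycle (22 and 0 of 26, 4.9e-10, and 0.0955), nuclear respiratory chain (39 and 0 of 39, 3.1e-14, and 0.113), p53 targets (12 and 1 of 14, 4.6e-04, and 0.156), splicing regulators of muscle and stem cells (10 and 7 of 19, 0.0405, and 0.139) and cytosolic ribosomal proteins (0 and 30 of 30, 1.0e-06, and 0.38). The second value in each case was with an estimated correlation. The splicing call was also lost without iPSC replicate 1 or 2, mesoderm replicate 1 or 2 or cardiomyocyte replicate 2 (camera adjusted p 0.0522 to 0.246) and with the replicate block (0.34). Not called were the definitive endoderm (6 and 6 of 15), neuroectoderm (1 and 6 of 8), Nodal and BMP pathway (6 and 8 of 16), epithelial junction and adhesion (2 and 13 of 15), mesenchymal transition (10 and 3 of 14) and pacemaker-type (7 and 4 of 11). The same held for skeletal muscle (1 and 3 of 8), epicardial (2 and 1 of 6), blood (0 and 2 of 3), glycolysis (7 and 3 of 18), mitochondrial genome (1 and 0 of 13), cholesterol synthesis (2 and 6 of 16), hypoxia response (5 and 3 of 14) and replication-dependent histones (3 and 1 of 5), with camera adjusted p from 0.0544 (epithelial junction and adhesion) to 0.953 (definitive endoderm). The epithelial list was called when any of 11 libraries was left out (camera adjusted p 0.00194 to 0.0471) and the mesenchymal list (0.0616) without cardiomyocyte replicate 2, 3 or 4 (0.00916, 0.0406 and 0.0491). With the replicate block both were called (0.0124 and 0.0283). In glycolysis 4 rose without mesoderm replicate 3 or cardiomyocyte replicate 3 or 4 or by upper quartile, and 3 by library totals. In the mitochondrial genome list 4 rose without cardiomyocyte replicate 1 and 8 without both doubted libraries.

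The third question was how cardiomyocytes differ from the iPSC they came from. Stem cell genes were silenced. ESRG (ENSG00000265992.1) (chromosome 3, 54632122 to 54639857), a non-coding RNA of pluripotent cells, fell from 978 ± 51.3 to 0.143 ± 0.0492 CPM (log2 change -12.71, SE 0.25). POU5F1 went from 1458 ± 25.2 to 0.400 ± 0.158 CPM (-11.82, SE 0.25). DPPA4 (ENSG00000121570.12) went from 772 ± 22.3 to 0.505 ± 0.137 CPM (-10.55, SE 0.20). NANOG went from 135 ± 6.85 to 0.0702 ± 0.0617 CPM (-10.80, SE 0.31). SOX2 went from 179.9 ± 10.2 to 0.214 ± 0.178 CPM (-9.70, SE 0.33, and -10.31 without cardiomyocyte replicate 1). DNMT3B went from 3172 ± 238 to 13.8 ± 7.51 CPM (-7.84, SE 0.48). ZSCAN10 (ENSG00000130182.8) (149.6 ± 10.4 CPM, at least 4259.8-fold) and ZFP42 (92.8 ± 4.23 CPM, at least 2643-fold) fell to 0 counts. These had edgeR adjusted p between 1.6e-11 (ESRG and DPPA4) and 5.8e-08 (DNMT3B). In the pluripotency list 0 of 28 rose, 27 fell and 1 was not called (28 fell over the list alone, median -8.24, or -7.90 with genes of 0 counts at their bound, camera adjusted p = 5.6e-38, and 2.4e-04 with an estimated correlation), and 28 fell without the doubted libraries.

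Heart muscle genes made the opposite change. From 0 counts in iPSC, MYL4 (ENSG00000198336.9), an atrial and fetal light chain gene, reached 3469 ± 612 CPM (at least 80942-fold), MYL3 (ENSG00000160808.10), the ventricular essential light chain gene, 2075 ± 713 CPM (at least 48410.5-fold), PLN 2217 ± 985 CPM (at least 51732-fold), NKX2-5 112 ± 35.7 CPM (at least 2622-fold) and MYL2 51.1 ± 45.3 CPM (at least 1192-fold). Also from 0 counts, the stretch-responsive gene ANKRD1 (ENSG00000148677.6) reached 6008 ± 6976 CPM (at least 140167-fold, with 16346, 1038, 3308 and 3338 CPM in the 4 libraries) and NPPA 1339.9 ± 1635 CPM (at least 31263-fold). Without cardiomyocyte replicate 1 the log2 change was 18.89 for ANKRD1 (20.10 with it), 16.65 for NPPA (17.94) and 12.41 for MYL2 (13.23). MYH7 went from 2 counts to 14766 ± 3676 CPM (ratio 516791, 95% counting interval 143063 to 4267310.0). MYH6 went from 0.121 ± 0.183 to 5911 ± 3439 CPM (log2 change 15.44, SE 1.08, and 17.05 without iPSC replicate 3). MYL7 (ENSG00000106631.8), the atrial light chain gene, went from 0.630 ± 0.207 to 8258 ± 3661 CPM (13.69, SE 0.57). TNNT2 went from 2.01 ± 0.730 to 2429 ± 663 CPM (10.22, SE 0.35). TTN went from 35.1 ± 3.65 to 19082 ± 4189.6 CPM (9.09, SE 0.22). These had edgeR adjusted p between 4.1e-11 (TTN) and 0.0003 (MYL2). In the sarcomere and Z disc list 37 of 38 rose, 0 fell and 1 was not called (the same over the list alone and without the doubted libraries, median 10.18, or 9.98 with genes of 0 counts at their bound, camera adjusted p = 6.6e-44, and 2.4e-06 with an estimated correlation).

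The lists of atrial and ventricular genes rose. In the atrial-type list 8 of 10 rose, 0 fell and 2 were not called (the same over the list alone, median 3.97, camera adjusted p = 5.0e-04, and 0.0285 with an estimated correlation), and 9 rose and 1 fell without the doubted libraries (1 fell without cardiomyocyte replicate 1). In the ventricular-type list 9 of 9 rose (9 over the list alone and without the doubted libraries, median 13.23, or 10.22 with genes of 0 counts at their bound, camera adjusted p = 6.4e-07, and 0.0955 with an estimated correlation). The pacemaker-type list was divided, with 7 of 11 up, 3 down and 1 not called (7 and 4 over the list alone and without the doubted libraries, median 1.53, camera adjusted p = 0.428). The pacemaker channel gene HCN4 (ENSG00000138622.4) rose from 15.8 ± 1.52 to 176 ± 30.5 CPM (log2 change 3.47, SE 0.14). The factor TBX3 (ENSG00000135111.16) went from 0.112 ± 0.131 to 20.3 ± 10.9 CPM (7.57, SE 0.74, and 8.34 without iPSC replicate 2). The calcium sensor gene VSNL1 (ENSG00000163032.12) fell from 67.8 ± 7.18 to 0.294 ± 0.2496 CPM (-7.83, SE 0.38), and these had edgeR adjusted p from 2.5e-09 (HCN4) to 2.6e-06 (TBX3). Within cardiomyocytes, MYH7 made up 74.1 ± 12.9% of MYH6 and MYH7 together (n = 4, 93.1% in replicate 1, and 67.7 ± 3.22% without it). The adult troponin TNNI3 made up 3.80 ± 4.11% of TNNI3 and TNNI1 (9.96%, and 1.75 ± 0.259%) and MYL2 1.22 ± 1.86% of MYL2 and MYL7 (4.00%, and 0.285 ± 0.0716%). The fetal troponin and the atrial light chain thus dominated.

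Genes of mitochondrial energy supply rose, while glycolysis was not called. The pyruvate carrier gene MPC1 (ENSG00000060762.19) rose from 5.12 ± 0.724 to 65.9 ± 14.2 CPM (log2 change 3.69, SE 0.19) and IDH3A (ENSG00000166411.14) of the TCA cycle from 27.04 ± 3.65 to 221 ± 30.9 CPM (3.03, SE 0.13), with edgeR adjusted p of 1.3e-08 and 4.1e-09. LDHB (ENSG00000111716.13), which turns lactate into pyruvate, was not called (1073 ± 27.9 and 1041 ± 134 CPM, -0.04, SE 0.10, edgeR adjusted p = 0.711), but fell by 0.41 on the log2 scale when scaled by library totals only. In the lactate oxidation and TCA cycle list 22 of 26 rose, 0 fell and 4 were not called (the same over the list alone, median 1.47, camera adjusted p = 5.5e-09, and 0.117 with an estimated correlation). Without the doubted libraries 24 rose and 1 fell, and 1 fell without cardiomyocyte replicate 1 or 2. In the nuclear respiratory chain list 39 of 39 rose (39 over the list alone and without the doubted libraries, median 1.25, camera adjusted p = 4.7e-11, and 0.15 with an estimated correlation). The muscle subunit gene COX6A2 (ENSG00000156885.6) rose from 0.109 ± 0.108 to 11.1 ± 6.86 CPM (6.70, SE 0.77, and 7.54 without iPSC replicate 1). NDUFA9 (ENSG00000139180.11) of complex I went from 24.1 ± 8.45 to 113 ± 7.59 CPM (2.23, SE 0.21). The ATP synthase gene ATP5F1B (ENSG00000110955.9) went from 751 ± 35.7 to 1819 ± 305 CPM (1.28, SE 0.12), and these had edgeR adjusted p from 1.9e-06 (NDUFA9) to 5.5e-05 (COX6A2). In the fatty acid oxidation list 21 of 25 rose, 1 fell and 3 were not called (the same over the list alone, median 1.81, camera adjusted p = 7.7e-08, and 0.34 with an estimated correlation). With the doubted libraries out 22 rose and 1 fell, and 2 fell without cardiomyocyte replicate 2. FABP3 rose from 7.59 ± 0.742 to 361 ± 56.3 CPM (5.57, SE 0.15). PPARGC1A went from 4.15 ± 0.148 to 167 ± 36.6 CPM (5.33, SE 0.19). HADHA went from 158 ± 3.28 to 377 ± 59.2 CPM (1.25, SE 0.11). The lipase gene LPL (ENSG00000175445.17) fell from 12.0 ± 0.690 to 2.21 ± 0.378 CPM (-2.44, SE 0.22), and these had edgeR adjusted p from 1.3e-10 (FABP3) to 1.4e-06 (HADHA). In the glycolysis list 4 of 18 rose, 5 fell and 9 were not called (4 and 2 over the list alone, camera adjusted p = 0.908). Without the doubted libraries 7 rose and 6 fell, 7 rose without cardiomyocyte replicate 1, and 2 or 3 fell without any 1 iPSC library. The kinase gene PFKP (ENSG00000067057.17) rose from 113 ± 7.77 to 1064 ± 232 CPM (3.23, SE 0.18, edgeR adjusted p = 2.6e-08) and the glucose carrier gene SLC2A1 (ENSG00000117394.23) fell from 236 ± 48.5 to 58.1 ± 3.04 CPM (-2.02, SE 0.13, edgeR adjusted p = 1.1e-07). GAPDH (ENSG00000111640.15) was not called (3637 ± 211 and 3478 ± 1247 CPM, -0.06, SE 0.24, edgeR adjusted p = 0.821), and without cardiomyocyte replicate 1 it was called as higher (0.17, edgeR adjusted p = 0.0355).

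Regulators of splicing moved both ways. RBM24 (ENSG00000112183.15), a muscle splicing factor, rose from 0.427 ± 0.0847 to 285 ± 59.6 CPM (log2 change 9.36, SE 0.27). RBM20 (ENSG00000203867.8), which controls titin splicing, went from 0.826 ± 0.116 to 319 ± 49.9 CPM (8.58, SE 0.26). ESRP2 (ENSG00000103067.14), an epithelial splicing factor, fell from 41.7 ± 2.05 to 3.32 ± 2.75 CPM (-3.63, SE 0.54). The general factor HNRNPA1 (ENSG00000135486.17) went from 1681 ± 82.1 to 496 ± 165 CPM (-1.76, SE 0.23), and these had edgeR adjusted p from 1.6e-10 (RBM24) to 8.4e-05 (ESRP2). In the splicing regulators of muscle and stem cells list 10 of 19 rose, 7 fell and 2 were not called (the same over the list alone, median 1.31, camera adjusted p = 0.0244). It had 11 up and 6 down without the doubted libraries. That list call was lost with an estimated correlation (camera adjusted p = 0.144), with the replicate block (0.248), without mesoderm replicate 2 (0.146) and without cardiomyocyte replicate 2 (0.0706). The skeletal muscle list was not called as a group (2 of 8 up, 4 down and 2 not called, the same over the list alone, median -2.21, or -0.88 with genes of 0 counts at their bound, camera adjusted p = 0.613). The creatine kinase gene CKM (ENSG00000104879.5), shared with heart, rose from 0 counts to 137 ± 114 CPM (at least 3204-fold, edgeR adjusted p = 0.000414, with 26.7, 296, 127 and 99.5 CPM in the 4 libraries, log2 change 14.65, and 13.98 without cardiomyocyte replicate 2) and the fast myosin gene MYH1 (ENSG00000109061.10) fell from 3.13 ± 0.257 CPM to 0 counts (at least 89.2-fold, edgeR adjusted p = 5.9e-05). With the doubted libraries out 5 fell, and 1 rose without iPSC replicate 3.

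Some early genes did not return to their starting level. AXIN2 ended below iPSC (26.4 ± 5.63 and 13.5 ± 2.11 CPM, log2 change -0.97, SE 0.16), while MIXL1 (2.34 ± 0.565 and 5.61 ± 1.31 CPM, 1.27, SE 0.20) and EOMES (0.192 ± 0.141 and 0.639 ± 0.238 CPM, 1.66, SE 0.45) stayed slightly above it, and these had edgeR adjusted p from 0.000154 (MIXL1) to 0.00566 (EOMES). MESP1 (0.222 ± 0.163 CPM, at least 5.19-fold, edgeR adjusted p = 0.00677) and SOX17 (1.01 ± 0.889 CPM, at least 23.5-fold, edgeR adjusted p = 0.00581) had 0 counts in iPSC. TBXT was not called (0.131 ± 0.151 CPM and 2 counts, edgeR adjusted p = 0.109), though it was without iPSC replicate 4 (0.0369) or cardiomyocyte replicate 1 (0.0363). MKI67 fell from 302 ± 2.67 to 66.5 ± 49.2 CPM (-2.18, SE 0.73, edgeR adjusted p = 0.0189, and 0.0528 with only the 2 groups fitted), and COL1A1 rose from 109 ± 3.47 to 256 ± 128 CPM (1.23, SE 0.31, edgeR adjusted p = 0.00407). Over all genes 6697 were higher and 7088 lower (68.7% of those tested, 4505 and 5052 by at least 2 fold, 1243 and 1982 by at least 8 fold), and 7715 and 8287 without the doubted libraries. Scaled by library totals only the numbers were 4911 and 9046 (35.2% up instead of 48.6%, median of all genes -0.38), and the median was -0.19 by upper quartile.

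Of the remaining lists, those called were the presomitic and paraxial mesoderm (2 up and 7 down of 9, camera adjusted p = 0.00466, and 0.235 with an estimated correlation), epithelial junction and adhesion (2 and 13 of 15, 0.024, and 0.752), mesenchymal transition (11 and 2 of 14, 3.6e-04, and 0.179), cardiac transcription factors (25 and 0 of 25, 1.4e-17, and 0.003), calcium handling (15 and 0 of 16, 6.2e-15, and 0.0132), smooth muscle (8 and 1 of 11, 0.00235, and 0.335), cell division (0 and 24 of 24, 0.00466, and 0.793), DNA replication (0 and 21 of 22, 2.2e-04, and 0.644) and cytosolic ribosomal proteins (0 and 30 of 30, 3.8e-05, and 0.494). The second value in each case was with an estimated correlation. Without cardiomyocyte replicate 1 the presomitic (0.0684) and epithelial (0.0938) list calls were lost. Not called were the primitive streak and nascent mesoderm (13 and 7 of 28), definitive endoderm (12 and 1 of 15), neuroectoderm (0 and 4 of 8), canonical Wnt targets and feedback (7 and 5 of 18), Nodal and BMP pathway (8 and 7 of 16), cardiac ion channels and connexins (14 and 6 of 25) and fibroblast and stroma (6 and 4 of 12). The same held for epicardial (3 and 1 of 6), endothelial (3 and 9 of 13), blood (1 and 2 of 3), mitochondrial genome (8 and 0 of 13), cholesterol synthesis (2 and 8 of 16), hypoxia response (5 and 4 of 14), p53 targets (7 and 2 of 14) and replication-dependent histones (2 and 3 of 5), with camera adjusted p from 0.0544 (cardiac ion channels and connexins) to 0.859 (Nodal and BMP pathway). Of these, the ion channel list was called without mesoderm replicate 1, 3 or 4 or cardiomyocyte replicate 3 or 4 (camera adjusted p 0.0372 to 0.0454), the endoderm list (0.0646) without mesoderm replicate 1, 2 or 3 or cardiomyocyte replicate 2 (0.00459 to 0.0477) or with the replicate block (0.0103), and the mitochondrial genome list (0.259) without mesoderm replicate 2 (0.00981). Without cardiomyocyte replicate 1, 5 p53 targets fell and 5 endothelial genes rose (5 too without mesoderm replicate 2), 5 epicardial genes rose without cardiomyocyte replicate 2, 2 hypoxia genes fell without iPSC or cardiomyocyte replicate 4, and the mitochondrial genome list had 3 to 5 up without any 1 iPSC library or cardiomyocyte replicate 2, 3 or 4. It had 5 up with the replicate block, 3 by upper quartile and 1 by library totals. Cytosolic ribosomal protein genes held 3.10 ± 0.0338% of counts in iPSC, 3.19 ± 0.209% in mesoderm and 1.23 ± 0.208% in cardiomyocytes, and the 20 most abundant genes 9.08 ± 0.209%, 10.9 ± 2.04% and 15.5 ± 1.21% (n = 4 per group, exact permutation p = 0.0286, adjusted p = 0.0476 for cardiomyocytes against each other group). The 13 mitochondrial messenger RNAs held 4.80 ± 0.177%, 5.94 ± 2.37% and 6.64 ± 2.05% (n = 4 per group, exact permutation p = 0.486 for mesoderm against iPSC, 0.457 for cardiomyocyte against mesoderm and 0.143 for cardiomyocyte against iPSC).

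The last question was which genes stood apart in mesoderm from both other groups. Genes higher in mesoderm than in both iPSC and cardiomyocytes numbered 1635, among them EOMES, MIXL1, TBXT, CER1, DKK4 and AXIN2 named above, and genes lower than in both numbered 1447. Both comparisons share the mesoderm libraries, so overlap arises by itself. Independent lists of these sizes would share 1247 and 1186. With 2 mesoderm libraries set against iPSC and the other 2 against cardiomyocytes, 1085 to 1193 genes were higher and 772 to 858 lower over 6 divisions. The numbers were 2878 and 2272 without the doubted libraries, and 2781 and 2227 without cardiomyocyte replicate 1.

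**Figure D4:**
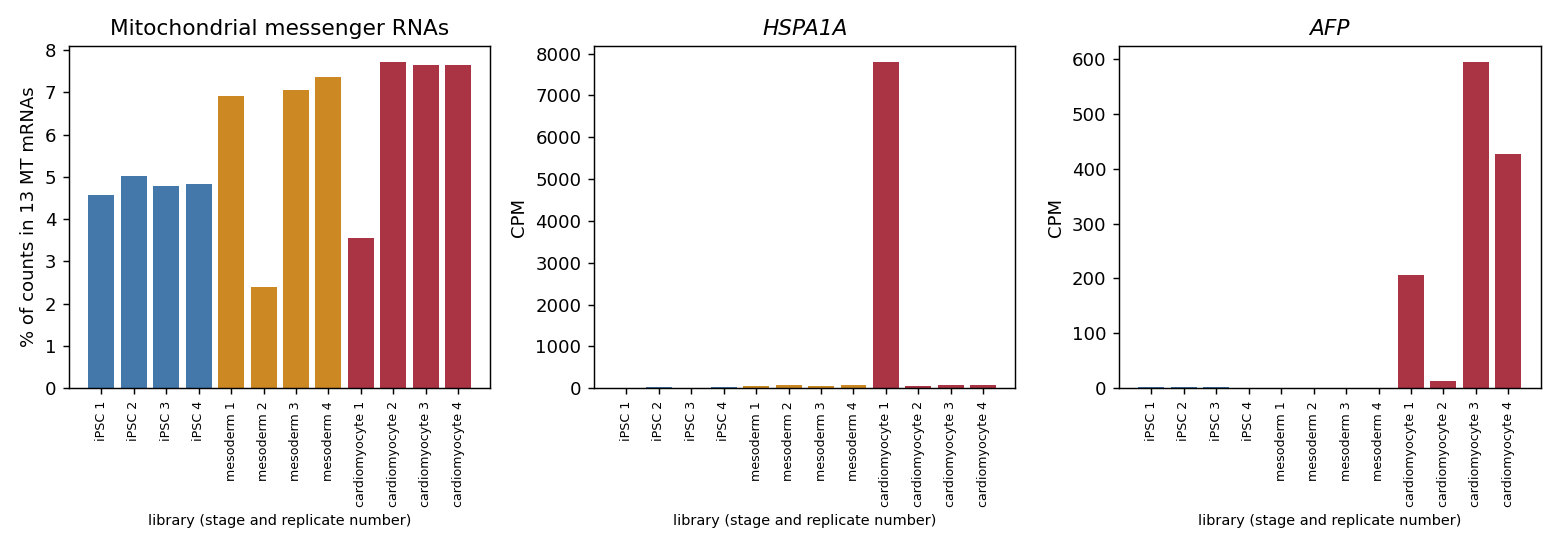
Values per library, 4 libraries per group: percent of counts in the 13 mitochondrial messenger RNAs, HSPA1A in CPM and AFP in CPM.

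Libraries within a group differed in sets of genes that moved together, chosen after values were seen. Cardiomyocyte replicate 1 had more heat shock and protein folding messages than the other 3: all 15 of 15 heat shock genes (median log2 difference 2.78) and 15 of 16 genes of the unfolded protein response (2.48) lay above all 3 others, with HSPA1A at 7794 against 54.6 to 81.8 CPM, HSP90AA1 at 13730 against 983 to 1389 CPM and HSPA5 at 9358 against 387 to 734 CPM. In the same library 23 of 24 cell division genes lay below all 3 others (median -3.12), and NPPB stood at 3568 against 32.4 to 384 CPM. Mesoderm replicate 2 had 2.40% of counts in mitochondrial messenger RNAs against 6.92 to 7.37% in the others. AFP had 206, 12.8, 594 and 426 CPM in the cardiomyocyte libraries, and the secreted protease inhibitor gene SERPINA1 22.5, 5.97, 393 and 334 CPM. Some single values near 0 may come from the counting. MT-ND3 was at 0 in iPSC replicate 3 against 589 to 660 CPM in the other iPSC libraries. TUBB3, at an overlapping locus, was at 0.257 CPM in cardiomyocyte replicate 2 against at least 32.4 CPM in the others.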

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

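These values were picked by a Dixon test for 1 value of 4 apart from the others, run after the data were seen. It picks out about 1 in 20 groups by chance, and it picked 6 of 30 library measures and 25 of 180 gene values (9 expected). Cardiomyocyte replicate 1 gave 14 of these gene values, more than any other library. In it, mitochondrial messenger RNAs held 3.559% of counts (others 7.641 to 7.716%), histones 0.004283% (0.001179 to 0.001343%), TNNI3 9.962% of both troponins (1.54 to 2.037%) and MYL2 4.004% of both light chains (0.2376 to 0.3677%). In CPM, it was lower than the others in MYH6 (779.9, others 7135 to 7985), GAPDH (1627, 3843 to 4236), RSPO3 (8.204, 175.1 to 205.7), HAND1 (25.54, 138.5 to 146.9), BMP2 (15.89, 43.64 to 48.63) and HNRNPA1 (250.5, 556.3 to 591.2), and higher in ANKRD1 (16350, 1038 to 3338), CSRP3 (3624, 609.7 to 838.3), MYOZ2 (1327, 412.7 to 450.9), COL3A1 (705.2, 39.8 to 70.93), IDH3A (266.9, 202.5 to 209.1), ZEB2 (155.9, 39.48 to 52.25), MYL2 (118.7, 23.45 to 34.79) and LUM (112, 3.037 to 14.3).

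Mesoderm replicate 2 had 2.404% of counts in mitochondrial messenger RNAs (others 6.921 to 7.374%), less NANOG (46.48 CPM, 61.36 to 64.37), SOX2 (24.95, 32.07 to 33.13) and RRM2 (113.3, 129.2 to 132), and more HADHA (240.7, 210.9 to 215.7), ZSCAN10 (107.3, 70.73 to 76.14), PFKP (102.7, 74.49 to 75.03) and HCN4 (12.4, 10.74 to 10.91). MKI67 was low in mesoderm replicate 1 (337.4 CPM, 394.1 to 400.1), and mitochondrial ribosomal RNAs were high in cardiomyocyte replicate 2 (1.465%, 0.7535 to 0.8016%). In iPSC replicate 2, GJA1 was high (899.8 CPM, 808.4 to 823.5) and HADHA (153.6, 159.6 to 160.4) and HCN4 (13.58, 16.49 to 16.83) low.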

How the results depend on the processing

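Of 27 other settings, 2 were chosen after the data were seen (both doubted libraries left out, and library weights). A test against a 2-fold change gave 791 genes higher and 1018 lower in mesoderm vs iPSC, 3026 and 3547 in cardiomyocyte vs mesoderm, 3255 and 3878 in cardiomyocyte vs iPSC, 386 genes highest and 295 lowest in mesoderm, fewer by construction. Mesoderm vs iPSC gave 5891 higher and 5860 lower with only these groups fitted, 5808 and 5600 without both doubted libraries, and 7166 and 7148 with library weights. Genes highest and lowest in mesoderm were then 2878 and 2272 without both, and 3759 and 3047 with weights. With 1 library left out, mesoderm vs iPSC ranged from 2863 (without iPSC replicate 4) to 5642 (without cardiomyocyte replicate 1) higher and 2900 to 5515 lower, cardiomyocyte vs mesoderm from 6143 to 7287 and 6732 to 8109, cardiomyocyte vs iPSC from 6406 to 7547 and 6790 to 8143, genes highest in mesoderm from 1326 to 2781 and lowest from 1091 to 2227. GAPDH in cardiomyocyte vs iPSC (-0.06) ranged from -0.17 (without cardiomyocyte replicate 4) to 0.17 (without replicate 1), and was 0.17 without both and 0.20 with weights. An estimated correlation ended 30 list calls, and fry, which tests each list by itself, called 33 that camera did not. For the others that moved, the cause was not tested.

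Replicate numbers might pair libraries across groups. With the number as a block, the counts were 3170 and 3246, 6026 and 6919, 6289 and 7018, with 1458 genes highest and 1262 lowest in mesoderm. Residuals of same-numbered libraries correlated at -0.081 to 0.046, so no pairing was seen.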

Other observations

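Every test here was chosen after the result was seen. Among genes the report leaves out, the liver list differed between cardiomyocyte libraries: APOB had 1.754, 10.5, 134.6 and 114 CPM and TTR 12.07, 9.47, 79.12 and 58.99 CPM, while ALB stayed at or below 1.414 CPM. Dividing the 8 libraries of each comparison into 4 and 4, with a fit of those 8 alone, called as many genes as the real grouping in 1 of 35 divisions, the real one, in each comparison (11751, 11688 and 12398 genes, with at most 1, 0 and 0 in any other).

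Cardiomyocyte replicate 1 differed from the others in stress, stromal and cell cycle genes. Its 24.1 M counts lay above the lowest other total (21.7 M), against shallower sequencing, and sarcomere genes held 7.705% of its counts, against a mislabelled earlier stage. More stromal cells, which metabolic selection is meant to remove, could have raised COL1A1 and COL3A1 (COL1A2 was lower, 216.1 CPM against 383.4 to 776.1), but over 12 stromal genes the median log2 difference was 0.77, with 6 above and 4 below all others, which leaves this open. Dilution by other cells would lower sarcomere genes alike, but of 38 such genes 16 were above and 19 below all others (9 and 5 of them by at least 2 fold, median -0.27). It is thus unlikely as the only explanation, and some dilution stays open. Culture age (25 to 30 days, not given per library) stays open too, untested. The shares of MYH7, TNNI3 and MYL2 were higher in replicate 1, and cell division genes lower (median -3.12).

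Mitochondrial messenger RNAs were low in mesoderm replicate 2, 13 of 13 (median log2 difference -1.66, -2.4999 to -1.16). Its 24.9 M counts were the lowest of the 4 totals (others 28.8 to 35.7 M). However, the 4 iPSC libraries had fewer counts (13.1 to 18.7 M) and larger shares (4.58 to 5.01%, against 2.40% here). Cardiomyocyte replicate 2 had 21.7 M counts and a share of 7.72%. These values argue against shallower sequencing as the cause of the low share. Fewer mitochondria could lower all such RNAs alike, but the log2 differences spanned 2.165 (at most 0.400 in other mesoderm libraries), with the ribosomal RNAs at -0.60 and -0.33. The design names no biological difference within the group, and no other was tested.

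Liver and foregut genes varied between cardiomyocyte libraries, AFP by a ratio of 46.34, too much for depth. Carry-over from iPSC or mesoderm libraries is unlikely, as AFP reached at most 1.659 CPM there. Endoderm-derived epithelial cells in some cultures may explain it: 12 of 15 epithelial genes were lowest in replicate 2 and highest in replicate 3, as AFP was. Chance gives 1 gene in 12 that order, but these genes vary together (estimated correlation 0.654 to 0.694 over the comparisons). They are thus not separate pieces of evidence, and the explanation stays open. The order was also found before the test was written, and metabolic selection is meant to remove such cells.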
